A study of Halalkalibacterium halodurans with 8 samples.

How the data were processed

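RNA in 8 libraries from the alkaliphilic bacterium Halalkalibacterium (formerly Bacillus) halodurans, strain C-125, was measured by RNA sequencing. Per the labels, the design crosses genotype (wild type, or a knockout lacking ole and oap) with treatment (before ethanol, or after 3 hours in 5% (v/v) ethanol), with 2 libraries in each of the 4 groups, lettered A and B. Cells were grown at 37 °C in rich alkaline medium of about pH 10.5 to an optical density of 0.2 to 0.3, divided into 3 ml portions and kept in closed, shaken tubes during treatment, and 3 tubes were pooled for each RNA preparation. The protocol describes no mock treatment for the untreated libraries, so ethanol is not separated here from time in the closed tubes. Nothing in the labels says that libraries A and B of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

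Per the labels, ribosomal RNA was depleted from total RNA with a commercial bacterial kit before library preparation and paired-end Illumina sequencing. The deposited values are raw counts, the total reads mapped to each gene of the wild-type C-125 reference, per the descriptive note deposited with them; they are not normalized. Aligner, counter, their versions, strand and the treatment of reads that map to several genes are not given in the sources used here. Counts of near-identical genes (the rRNA and tRNA copies), of overlapping genes and of antisense pairs are therefore uncertain. The same note warns of a lack of reads in the knockout between BH2778 and BH2783, because the knockout chromosome differs there from the reference.

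Each count table held 4174 genes, of which 25 were rRNA genes, 78 tRNA genes, 5 other RNA genes and 4066 protein genes, and 0 entries named no gene. Outside rRNA and tRNA, 894 genes carried a symbol and 3177 a locus tag alone; the files do not pair tags with symbols, so no name was assigned to a tag. No genome or annotation was used, and no coordinates are given; neighbours are given by the order of genes in the count tables. Total counts per library ranged from 3013584 to 5243604, and counts outside rRNA from 798453 to 1861944. A floor of 3 counts corresponded to 1.61 to 3.76 CPM of the counts outside rRNA; floors and intervals cover counting error only. Libraries of the same group differed by more than sampling noise, with chi-square per degree of freedom of 16.4 to 25.0 over genes with at least 20 counts, so each was kept as its own sample.

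Choices made before the data were examined were the groups, the tests, the gene lists, the rule for naming genes and 19 of the 21 alternative settings. Differential expression was tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) on the counts, with TMM scaling, filterByExpr with a minimum count of 10, a robust prior and means for the 4 groups over all 8 libraries, so that the groups shared an estimate of the spread. The 25 rRNA genes were left out of library sizes and tests because their share depends on the depletion; 3474 genes were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were ethanol over untreated in each genotype, knockout over wild type in each condition, and the difference between the ethanol responses of the genotypes (interaction). Log2 fold changes are given ± the standard error, computed as the fold change over the square root of F; levels are normalised CPM (each library scaled to the same total, after TMM scaling), given as mean ± SD over 2 libraries.

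Of 40 gene lists written by symbol pattern, 37 had a tested gene and 27 had at least 5, the minimum for a set test. For each list the called members were counted over all genes tested and adjusted over the list alone. The set test was camera (limma 3.58.1) with a preset correlation of 0.01, repeated with a correlation estimated from the data; fry tested whether the members moved on balance in a single direction, without comparing them with other genes. P-values were adjusted over the 27 lists of a comparison. tRNA genes and the genes around ole were counted as groups without an adjusted set test.

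Genes were named by a fixed rule: among called genes whose groups did not overlap and with a mean of at least 50 counts, the 12 largest rises and 12 largest falls with a symbol and the 2 largest of each with a tag only; where none passed, the 5 smallest p-values; and for lists up to 4 members, called members first, by size of change. Where a gene was at 0 in a group, its fold is a lower bound against 3 counts per library; where a group held 1 to 6 counts over its 2 libraries, a ratio of summed counts is given with its exact 95% interval.

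Simulated counts had the library sizes of these samples and, in every group, the mean levels of untreated wild type. The broad ethanol response was thus not simulated. On these counts the edgeR step was tested with 100 genes changed at each fold size. At 4-fold it recovered 80% of those genes for ethanol in wild type, 80% for ethanol in the knockout, 92% for genotype in untreated cells, 70% for genotype in ethanol and 51% for the interaction; at 2-fold these shares were 30%, 36%, 31%, 26% and 8%. In a simulation of the genotype comparison in ethanol over 3264 genes, a list of 40 genes raised 2-fold was called by camera with the preset correlation (adjusted p = 3.81e-42), by camera with the estimated correlation (adjusted p = 0.00218) and by fry (adjusted p = 0.00112). Those 40 genes were drawn at random and simulated independently, so this does not show what the tests detect in lists of co-regulated genes.

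The alternatives planned were other scalings (RLE, upper quartile), DESeq2 1.42.0, no filter or a stricter filter (50 counts in 2 libraries), rRNA genes kept, the 10 most abundant genes left out, only the 4 libraries compared, the letter or the culture as a block, a prior that is not robust, and each library left out in turn (8 fits). The 2 remaining alternatives, library totals as the only scaling and the omission of tRNA and other RNA genes, were chosen after seeing the data. Library measures, permutation tests and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.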

Results

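The count tables cover wild-type cells of H. halodurans C-125, a bacterium that grows in alkaline medium, and cells of a knockout labelled as deleted for ole and oap. OLE is a long, abundant noncoding RNA, and oap encodes the OLE-associated protein, a membrane protein that binds it. The question put by the design is how each genotype responds to acute ethanol stress. Total counts were 3481932 (A) and 4747735 (B) in untreated wild type, and 4018779 (A) and 5243604 (B) in ethanol-treated wild type. The knockout libraries held 3618491 (A) and 3787523 (B) counts untreated, and 3430375 (A) and 3013584 (B) with ethanol. Between 59.1% and 73.5% of these counts were rRNA despite its depletion. That left 798453 to 1861944 other counts per library, and a protein gene had a median of 26 to 78 counts. rRNA took a larger share in every ethanol library, 70.9% ± 2.31 against 61.0% ± 2.17 in untreated libraries (SD, n = 4 each; 2-sided exact permutation test, p = 0.0286, the smallest possible with 4 against 4). Adjusted over 4 library measures this p was 0.0381. The 10 most abundant genes outside rRNA, taken in each library separately and so not a fixed set, held 17.4% ± 2.44 of the remaining counts untreated. With ethanol they held 35.2% ± 3.87 (the same exact permutation test, p = 0.0286, adjusted p = 0.0381).

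The targeted RNA followed the genotype labels in all 8 libraries. OLE had 8867 (A) and 12462 (B) counts in untreated wild type and 51383 (A) and 48036 (B) with ethanol. It had 64 (A) and 88 (B) in the untreated knockout and 178 (A) and 59 (B) in the ethanol-treated knockout. The knockout level was 0.739% of wild type before ethanol and 0.289% after it. BH2780 is the locus of oap in the published literature on this strain, although the files give only the tag. It had 269 (A) and 450 (B) counts in untreated wild type and 117 (A) and 126 (B) in the untreated knockout. With ethanol the counts were 319 (A) and 497 (B) against 247 (A) and 100 (B). Its normalised level in the knockout was thus 35.7% of wild type before ethanol and 55.0% after it, so part of its signal remained. The deposited note warns of a lack of reads in the knockout between BH2778 and BH2783. Apart from OLE and BH2780, the genes from BH2778 to BH2783 stood in the untreated knockout at 95.7% (BH2781) to 108% (BH2778) of the untreated wild type. With ethanol OLE rose 8.16-fold in wild type (log2 3.03 ± 0.44, edgeR adjusted p = 2.22e-04), from 5829 ± 359.7 to 47592 ± 17134 CPM. In the knockout the residual OLE signal also rose (log2 1.68 ± 0.45, edgeR adjusted p = 0.00840), with 0.88 without the knockout library ethanol A and 2.17 without ethanol B. That call was lost without the knockout library untreated A or ethanol A. BH2780 rose in wild type by 0.93 ± 0.28 (edgeR adjusted p = 0.0151), a call lost without the wild-type library untreated A (adjusted p = 0.0691) or with library totals as the only scaling (adjusted p = 0.213). In the knockout its remaining signal rose by 1.56 ± 0.30 (edgeR adjusted p = 0.00127), with 0.96 without the knockout library ethanol A and 1.96 without ethanol B.

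**Figure D1:**
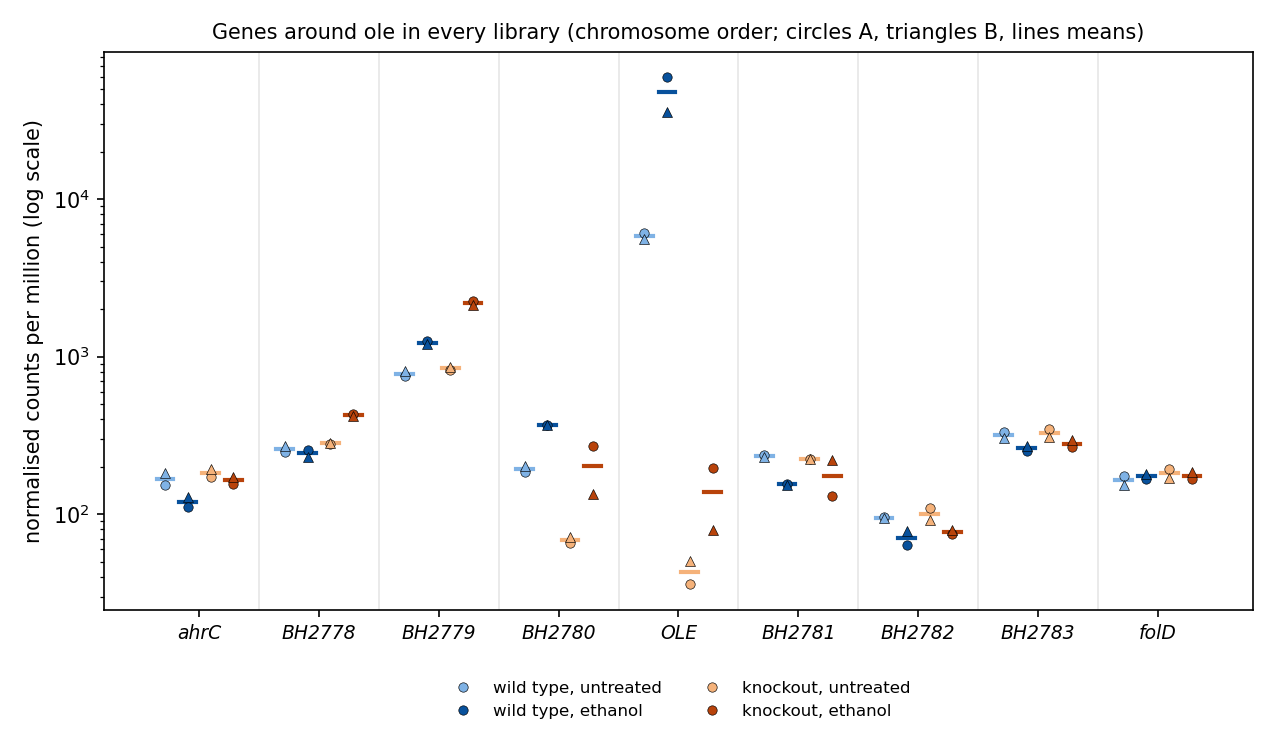
Normalised CPM (log scale) of OLE and its neighbours in each of the 8 libraries, in the order of the count tables; circles are libraries A, triangles libraries B and lines the means of 2. OLE lay near 5829 CPM in untreated and 47592 CPM in ethanol-treated wild type, and at 43.1 and 137 CPM in the knockout.

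The first comparison asks how wild-type cells responded to ethanol. pckA and gapB of gluconeogenesis, the ectoine gene ectC and most tested genes of the general stress and fatty acid degradation lists rose, while most tested genes of ribosomal proteins, flagella and tRNAs fell, as did fruA and fruB of fructose uptake. pckA, which encodes phosphoenolpyruvate carboxykinase, rose by log2 9.88 ± 0.42, from 7.34 ± 1.64 to 7140.2 ± 1366 CPM, and gapB, a glyceraldehyde phosphate dehydrogenase used in gluconeogenesis, by 9.19 ± 0.51 to 22506 ± 7724 CPM. ectC, the synthase of the compatible solute ectoine, rose by 5.35 ± 0.32, from 171 ± 18.4 to 6997 ± 1070.5 CPM, and dps, whose protein protects DNA in stressed cells, by 5.98 ± 0.31. Among the falls were lytE, a cell wall hydrolase (log2 -5.66 ± 0.28), treA, which splits trehalose phosphate (-5.57 ± 0.25), the fructose uptake gene fruA (-4.71 ± 0.81; -3.10 without the wild-type library untreated B and -5.44 without untreated A) and tdk, thymidine kinase (-4.59 ± 0.25). Of 3474 genes tested with edgeR's quasi-likelihood test, 2371 passed an adjusted p of 0.05, 1153 higher and 1218 lower with ethanol. With library totals as the only scaling, chosen after seeing the data, 34.5% of calls were rises in place of 48.6%, and the median of all genes moved from log2 -0.08 to -0.61.

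The rises in wild type also included dhaS, an aldehyde dehydrogenase gene (log2 7.73 ± 0.86), licH, a glycosidase gene (5.67 ± 1.02), rocD, for ornithine aminotransferase (5.16 ± 1.15), and the electron transfer flavoprotein genes etfA (5.41 ± 0.98) and etfB (5.28 ± 0.81). Among the falls were fruB (-5.04 ± 0.96), the flagellar export gene flhB (-4.65 ± 0.34), the ribosomal protein genes rplL (-4.63 ± 0.24) and rplJ (-4.60 ± 0.24), and 4 tRNA genes, trnK-Leu (-5.12 ± 0.47), trnG-Asp (-4.81 ± 0.33), trnJ-Phe (-4.76 ± 0.40) and trnG-Leu1 (-4.60 ± 0.27). edgeR adjusted p-values of the named genes ran from 1.46e-06 (pckA) to 0.0115 (BH1462). Of genes known only by tag, BH3544 held 5 counts over the untreated and 1241 over the ethanol libraries, a ratio of 414 (exact 95% interval 177 to 1277), and BH0538 held 1 and 361 counts, a ratio of 602 (interval 107 to 23841). BH0566 fell from 767 to 4 counts, a ratio of 0.00870 (interval 0.00236 to 0.0224), and BH1462 from 359 to 3, a ratio of 0.0139 (interval 0.00286 to 0.0411). Leaving out a wild-type untreated library moved licH (4.98 without A, 7.04 without B), rocD (4.34 and 7.62) and fruB (-5.81 and -3.25) by more than 1.5 times, and without ethanol A the changes were 4.14 for etfA, 4.13 for etfB and 6.52 for dhaS. These reached 6.75 for etfA and 6.19 for etfB without untreated A and 8.40 for dhaS without ethanol B, all still called. BH3544 and BH0538 had log2 changes of 7.92 and 7.89 without ethanol A. All their untreated counts lay in untreated B, so without it both were compared with 0 counts. BH0566 stood at -5.89 without ethanol B and BH1462 at -4.48 without untreated A. The call of BH1462 was lost without the wild-type ethanol library A (adjusted p = 0.0586) or B (adjusted p = 0.0829).

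Among the fixed gene lists, that of general stress regulators and proteins rose in wild type. By edgeR 9 of 11 tested members were higher and 0 lower at an adjusted p of 0.05 (9 adjusted over the list alone), with a median log2 change of 3.84. Outside sigB and its rsb regulator genes the list holds only dps, bmrU and opuE. The count thus describes mainly sigB and those regulators, not the sigma B regulon as a whole. Besides dps, the largest rises in the list were in the regulator genes rsbX (4.29 ± 0.31), rsbS (4.21 ± 0.34) and sigB itself (4.07 ± 0.30). The camera test gave an adjusted p of 3.15e-07, and an adjusted p = 0.387 with an estimated correlation. The tricarboxylic acid cycle list had 7 of 10 members higher (7 adjusted over the list alone), led by citZ, citrate synthase (2.08 ± 0.29), citH, malate dehydrogenase (1.99 ± 0.28), and citC, isocitrate dehydrogenase (1.95 ± 0.28); its adjusted p was 0.0459 by camera and its adjusted p = 0.795 with an estimated correlation, so this call was marginal. All 4 tested genes of fatty acid degradation rose (4 adjusted over the list alone), mmgA by 6.17 ± 1.19, mmgC by 5.44 ± 0.75, mmgB by 5.29 ± 1.03 and acdA by 4.80 ± 0.68; mmgA held 5 counts in the untreated libraries against 202, a ratio of 67.4 (exact 95% interval 28.4 to 209.7). Without the wild-type library ethanol A these changes were 4.35, 4.19, 3.93 and 3.58. They reached 7.63 (mmgA) and 6.85 (mmgB) without untreated A and 6.13 (mmgC) and 5.49 (acdA) without ethanol B, all still called. The glycolysis and gluconeogenesis list was divided, with 7 higher and 11 lower of 18 (7 and 11 adjusted over the list alone; camera adjusted p = 0.822). Against pckA and gapB stood pdhA of pyruvate dehydrogenase (-3.53 ± 0.24) and ackA, acetate kinase (-3.45 ± 0.26).

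Translation and motility genes fell in wild type. Of 53 ribosomal protein genes tested, 50 were lower and 1, rplY, higher (50 and 1 adjusted over the list alone), with a median of -3.22 and the largest falls in rplL, rplJ and rpsE (-4.29 ± 0.41). Of 41 flagellar, motility and chemotaxis genes 38 were lower and 2 higher (38 and 3 adjusted over the list alone), with a median of -3.64; fliQ stood at -4.51 ± 0.42 and hag, the flagellin gene, at -4.45 ± 0.35. The camera adjusted p was 1.93e-20 for ribosomal proteins and 2.69e-19 for flagella, and adjusted p = 0.300 with an estimated correlation for both. Of 21 translation and transcription factor genes 15 were lower and 2 higher (the same counts adjusted over the list alone), with fus, elongation factor G, at -3.78 ± 0.27 (camera adjusted p = 7.66e-05; adjusted p = 0.384 with an estimated correlation). Of 19 aminoacyl-tRNA synthetase genes 15 were lower (15 adjusted over the list alone; camera adjusted p = 0.00791; adjusted p = 0.795 with an estimated correlation). tRNA genes, counted without an adjusted set test, were lower in 73 of 76 cases (73 adjusted over the list alone), with a median of -3.32, and tRNA reads made up 0.198% ± 0.0353 of counts outside rRNA in the 4 ethanol libraries of both genotypes against 2.27% ± 0.385 in the 4 untreated libraries (exact permutation p = 0.0286, adjusted p = 0.0381).

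Histidine, tryptophan and purine synthesis genes were mostly lower. Of 22 genes of histidine and tryptophan synthesis 20 were lower (21 adjusted over the list alone), with a median of -2.11 and trpD at -4.33 ± 0.40 (camera adjusted p = 1.58e-04; adjusted p = 0.300 with an estimated correlation). Of 16 purine synthesis genes 14 were lower and 1 higher (the same adjusted over the list alone), with purK at -3.31 ± 0.50 (-2.75 without the wild-type library ethanol B and -3.92 without ethanol A; camera adjusted p = 0.0459; adjusted p = 0.795 with an estimated correlation). The ATP synthase list had 7 of 8 genes lower (7 adjusted over the list alone), with atpD at -1.997 ± 0.31, but its camera adjusted p was 0.0877. Of the heat shock chaperone genes controlled by HrcA, groES and groEL were higher, each by 0.67 (SE 0.26 and 0.25), and dnaJ lower (-0.98 ± 0.26) among 6 tested; adjusted over the list alone 0 were higher and 1 lower, and dnaK stood at 0.30 ± 0.27. Those 3 calls became 1 without the wild-type library ethanol A or ethanol B and 0 without untreated B, and both rises ended with no filter on low counts (adjusted p = 0.0538 and 0.0572) and when only library totals were scaled (adjusted p = 0.671 and 0.698). groEL was also lost without the knockout library untreated A (adjusted p = 0.0533) or untreated B (adjusted p = 0.0539). Of the alcohol and aldehyde dehydrogenase list, aldA rose by 2.76 ± 0.24 and adhB fell by 2.69 ± 0.51. Of 27 lists, camera called 8 with the preset correlation and 0 with the estimated correlation (3 at an unadjusted p under 0.05), and fry called 19.

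**Figure D2:**
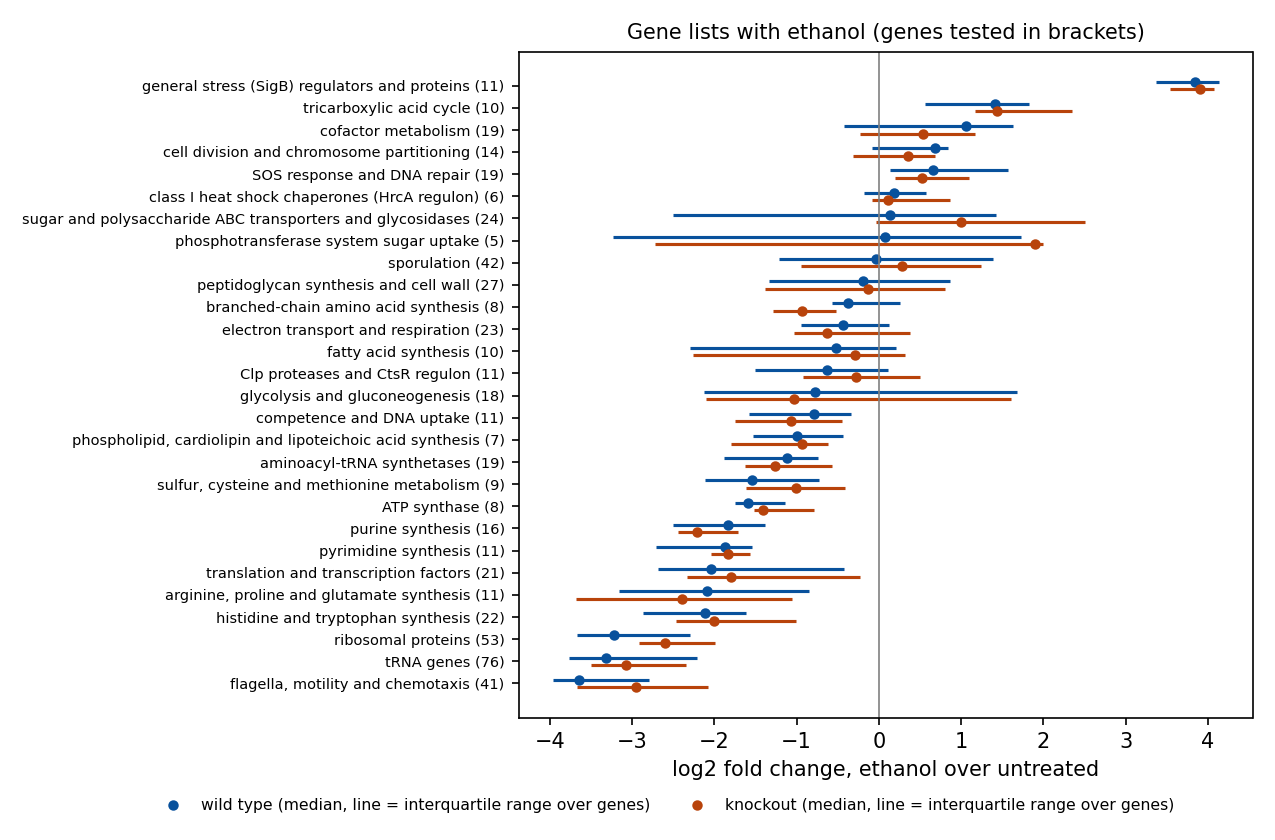
Median log2 fold change with ethanol of each gene list with at least 5 tested genes (points) and the interquartile range over its genes (lines), in wild type and knockout. The general stress list lies at 3.84 and 3.90, and ribosomal proteins, tRNA genes and flagella lie lowest in both genotypes.

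The same comparison was made in the knockout, where many of the same groups moved. pckA rose by log2 9.31 ± 0.41 and gapB by 8.74 ± 0.50, to 6009 ± 26.3 and 17899 ± 4810.5 CPM. Genes of histidine degradation were among the largest rises. Of these hutH, histidase, held 2 counts over the untreated libraries and 283 with ethanol, a ratio of 302 (exact 95% interval 82.8 to 2505), and hutU, urocanase, held 6 and 450, a ratio of 160.0 (interval 72.9 to 438), while hutI rose by 6.63 ± 0.43 and hutG by 5.96 ± 0.66. mmdA and mutB, of methylmalonyl-CoA metabolism, rose by 8.32 ± 1.67 and 7.69 ± 1.26, acsA, acetyl-CoA synthetase, by 5.998 ± 0.76, etfB by 6.79 ± 0.89 and etfA by 6.50 ± 1.05. msmE, for a sugar-binding protein, held 6 and 321 counts, a ratio of 114 (interval 51.9 to 313). In all, 2255 of 3474 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1104 higher and 1151 lower. With library totals as the only scaling, chosen after seeing the data, 38.1% of calls were rises in place of 49.0%, and the median of all genes moved from log2 -0.04 to -0.46. The call of mmdA was lost without the knockout library untreated A (adjusted p = 0.0627) or untreated B (adjusted p = 0.0521). Without untreated B the changes of hutI and hutG were 7.57 and 7.97, against 6.04 and 5.14 without untreated A.

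The falls in the knockout were led by lytE (log2 -5.02 ± 0.27), fruB (-5.003 ± 0.95), fruA (-4.95 ± 0.82) and treA (-4.94 ± 0.24), followed by blt, for a multidrug transporter (-4.52 ± 0.34), treR, the repressor of trehalose genes (-4.39 ± 0.22), and trnJ-Phe (-4.27 ± 0.39). Flagellar genes followed, with flhB at -4.43 ± 0.35, fliJ at -4.17 ± 0.51, fliP at -4.08 ± 0.29, and fliI and flhA both at -4.02 (SE 0.32 and 0.26). Without the knockout library ethanol A flhB stood at -5.37 and fliJ at -3.43, and without ethanol B fliJ stood at -5.45. edgeR adjusted p-values of the named genes ran from 2.07e-06 (pckA) to 0.0217 (BH1462). Of tag-only genes, BH1130 was at 0 in both untreated libraries and at 190 ± 28.2 CPM with ethanol, at least 112-fold higher than 3 counts per library, and BH2323 held 2 counts against 1154, a ratio of 1231 (exact 95% interval 340.0 to 10177). BH0324 held 345 counts untreated and 2 with ethanol, a ratio of 0.0124 (interval 0.00149 to 0.0450), and BH1462 held 307 and 3, a ratio of 0.0208 (interval 0.00428 to 0.0615). The call of BH1462 was lost without the knockout library untreated A (adjusted p = 0.0680), ethanol A (adjusted p = 0.136) or ethanol B (adjusted p = 0.0970).

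Lists were counted in the knockout in the same way. General stress genes were higher in 9 of 11 cases and lower in 1 (the same adjusted over the list alone), with a median of 3.90 and dps at 5.64 ± 0.31 (camera adjusted p = 1.20e-07; adjusted p = 0.413 with an estimated correlation). The tricarboxylic acid cycle had 9 of 10 higher (9 adjusted over the list alone), with citH at 2.64 ± 0.28 (camera adjusted p = 0.00550; adjusted p = 0.751 with an estimated correlation), and all 4 fatty acid degradation genes were higher (4 adjusted over the list alone). Ribosomal proteins were lower in 49 and higher in 1 of 53 cases (50 and 1 adjusted over the list alone), with a median of -2.60 and rpsL at -3.63 ± 0.23. Flagella, motility and chemotaxis were lower in 38 and higher in 1 of 41 cases (38 and 1 adjusted over the list alone), with a median of -2.95. Both had a camera adjusted p of 7.60e-17, and adjusted p = 0.413 with an estimated correlation. Translation factors (15 lower, 1 higher of 21; adjusted p = 0.456 with an estimated correlation), aminoacyl-tRNA synthetases (14 lower of 19) and purine synthesis (14 lower, 1 higher of 16) had camera adjusted p-values of 7.64e-05, 0.00565 and 0.00770, and for the last pair the adjusted p = 0.751 with an estimated correlation; the counts were the same adjusted over each list alone. Histidine and tryptophan synthesis had 19 of 22 genes lower (19 adjusted over the list alone), which became 12 without the knockout library untreated A (camera adjusted p = 0.00164; adjusted p = 0.413 with an estimated correlation). tRNA genes were lower in 72 of 76 cases, with a median of -3.07. camera called 8 of 27 lists with the preset correlation and 0 with the estimated correlation (2 at an unadjusted p under 0.05), and fry called 19.

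The responses of the genotypes, which share no library, lay close together: 991 genes were higher with ethanol in both, where 366 would be shared by independent lists of these lengths, and 1044 were lower in both, where 404 would be. A single gene was called in opposite directions. Across the 3474 genes, which are not independent replicates, the log2 changes had Pearson's r of 0.935 and Spearman's rho of 0.949. A further 335 genes were called in wild type alone and 219 in the knockout alone, which does not show that their responses differed; that was tested by the interaction.

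**Figure D3:**
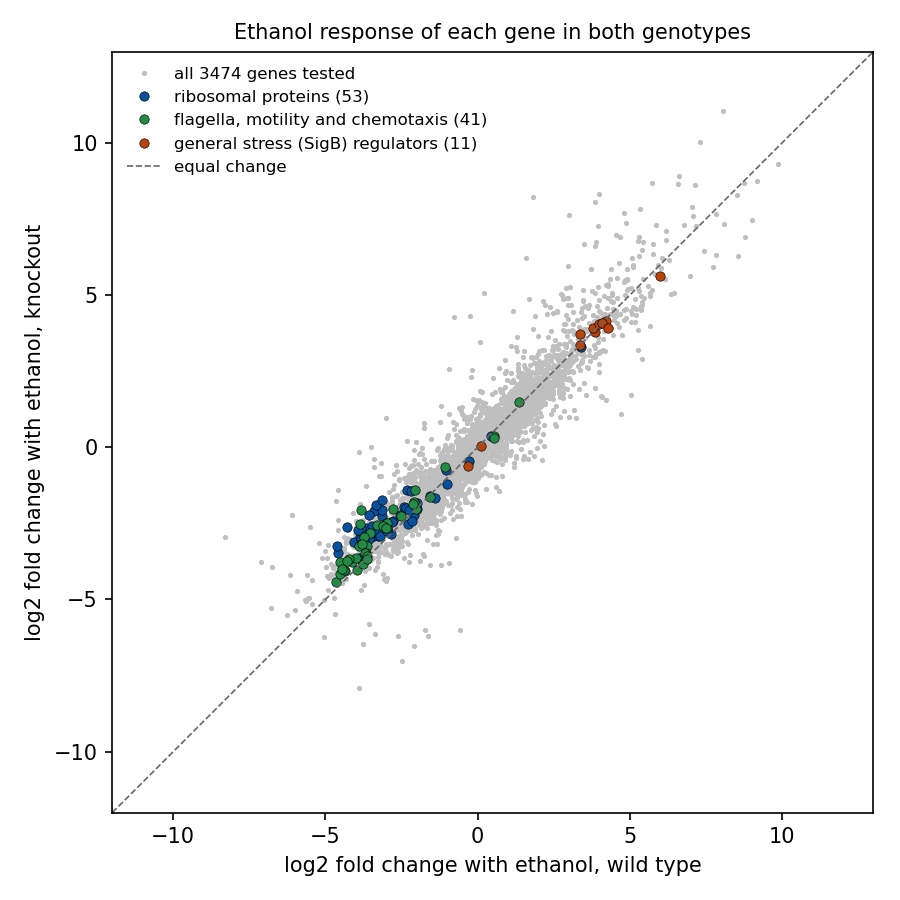
Log2 fold change with ethanol of each of 3474 genes in wild type (x axis) and knockout (y axis), with 3 gene lists in colour and a dashed line of equal change. Ribosomal protein genes, with medians of -3.22 in wild type and -2.60 in the knockout, lie mostly above the line at the lower left; the difference for the list was called with a preset but not with an estimated correlation.

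The next comparison asks how the knockout differed from wild type before ethanol. Only OLE passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, at 43.1 ± 10.2 CPM in the knockout and 5829 ± 359.7 in wild type (log2 -7.08 ± 0.54, adjusted p = 6.69e-04). BH2780 stood at log2 -1.49 ± 0.29 and missed the threshold (adjusted p = 0.490; with DESeq2 adjusted p = 0.0449). Its neighbour BH2779 was not called, at 778.6 ± 37.7 CPM in wild type and 841 ± 32.1 in the knockout (log2 0.11 ± 0.19, edgeR adjusted p = 1.00). An unadjusted p under 0.05 was reached by 69 of 3474 genes, fewer than that threshold would pass if no gene differed. These genes are thus no sign of differences beyond OLE. DESeq2 called 5 at an adjusted p of 0.05. The camera test called 5 of 27 lists, none with a called member: sugar transporters and glycosidases (median log2 -0.81, adjusted p = 3.76e-10), flagella (-0.20, adjusted p = 2.14e-04) and the tricarboxylic acid cycle (-0.38, adjusted p = 2.98e-04) were lower in the knockout, and ribosomal proteins (0.22, adjusted p = 3.07e-06) and purine synthesis (0.17, adjusted p = 0.0345) higher. Each had an adjusted p = 0.7497 with an estimated correlation, and fry, with 1 list at an unadjusted p under 0.05, called 0. The wild-type untreated library A stood over 3-fold apart from the median of the other 3 untreated libraries in 91 of 3473 genes, against 8 to 14 genes in each other library, and 9 of the 24 members of the sugar list were among them. Without that library the list medians were -0.14 for sugar transporters and glycosidases, -0.08 for flagella, -0.05 for the tricarboxylic acid cycle, 0.30 for ribosomal proteins and, turned in direction, -0.07 for purine synthesis. Lists that camera had not called could move away from 0 instead. The median of arginine, proline and glutamate synthesis, with 6 of 11 members among the 91 genes, went from -0.11 to 0.95. That of pyrimidine synthesis went from -0.14 to 0.88.

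With ethanol, the knockout held more mRNA of the histidine degradation genes hutH, hutU and hutI than wild type, and less of ilvD. A few ribosomal protein genes also differed, 5 of 53 tested, and these calls depended on single libraries; the list had a camera adjusted p = 0.388 with an estimated correlation. hutH stood at 174 ± 40.4 CPM in the knockout and 24.5 ± 1.84 in wild type (log2 2.81 ± 0.31, edgeR adjusted p = 0.00605), hutU at 274 ± 39.9 and 52.2 ± 10.05 (2.40 ± 0.25, adjusted p = 0.00587) and hutI at 233 ± 58.9 and 41.1 ± 5.93 (2.51 ± 0.32, adjusted p = 0.00903). hutG, adjacent to them in the count tables and named after its value was seen, missed the threshold (2.75 ± 0.52, adjusted p = 0.0501). Genes close together in the count tables were also higher in the knockout: rplO (1.67 ± 0.29), secY, for the protein translocation channel (1.75 ± 0.33), adk, adenylate kinase (1.77 ± 0.33), rpsM (1.68 ± 0.31) and rpsK (1.65 ± 0.31), with adjusted p-values of 0.0402 to 0.0466. The adjacent pair rplJ and rplL differed by 1.23 ± 0.21 and 1.47 ± 0.22, and clpY, the ATPase of a protease, by 1.27 ± 0.21. ilvD, of branched-chain amino acid synthesis, was lower in the knockout, at 816 ± 94.0 CPM against 2549 ± 247 (-1.64 ± 0.31, adjusted p = 0.0466), as was OLE (-8.43 ± 0.57, adjusted p = 2.16e-04; -9.23 without the knockout library ethanol A and -7.96 without ethanol B). Of tag-only genes, BH3280 (1.70 ± 0.26) and BH3123 (1.66 ± 0.22) were higher and BH3390 (-1.66 ± 0.20) and BH0055 (-1.49 ± 0.20) lower.

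In all, 34 of 3474 genes differed between the genotypes in ethanol at an adjusted p of 0.05 with edgeR, 27 higher and 7 lower in the knockout; 478 did at an unadjusted p under 0.05. The balance of directions turned without the wild-type library ethanol B (13 higher and 19 lower, 14 of these calls shared) and was nearly even without the knockout library ethanol B (18 and 16). The count was 7 without the knockout library ethanol A and 9 without the wild-type library ethanol A. It was 13 without the wild-type library untreated A or untreated B, 1 when only the 4 libraries compared were fitted, and 86 with DESeq2. hutH, hutI and hutU passed in 19 of 20 alternatives and missed the threshold only when those 4 libraries alone were fitted (adjusted p = 0.0587, 0.0683 and 0.0587). adk, secY, rpsM, rpsK, rplO, rplJ, clpY and ilvD each missed it without the knockout library ethanol A or any wild-type library (adjusted p from 0.0578 for clpY to 0.252 for ilvD). All 8 also missed it when only the 4 libraries compared were fitted. Other processing ended calls too: adk, secY, rpsM, rpsK and ilvD missed the threshold with upper-quartile scaling (adjusted p = 0.0543), with rRNA genes kept (0.0549) and without a robust prior (0.0606 to 0.0646). rplO and rplJ missed it with upper-quartile scaling (0.05004) and without a robust prior (0.0554 and 0.0528), and ilvD with library totals (0.0597). rplJ, clpY and ilvD also missed it without the knockout library ethanol B (adjusted p = 0.0728, 0.0936 and 0.128), and rplJ without either untreated knockout library (adjusted p = 0.0505 and 0.0503). Without the knockout library ethanol A the calls of rplL (adjusted p = 0.115), BH3280 (0.0937), BH3123 (0.0635), BH3390 (0.0604) and BH0055 (0.0937) were lost too. Without the wild-type library ethanol A so were those of rplL (0.0673), BH3280 (0.0783), BH3123 (0.0540) and BH0055 (0.0507). BH3280 was also lost without the library ethanol B of wild type (0.0589) or knockout (0.0536), and rplL without that of wild type (0.0826). Of 53 ribosomal protein genes 5 were higher (29 adjusted over the list alone) and 0 lower, by edgeR, with a median of 0.91. For this list camera gave an adjusted p of 6.89e-21, adjusted p = 0.388 with an estimated correlation, and fry an adjusted p of 0.0805. Those 5 calls became 0 without the library ethanol A of either genotype or the wild-type ethanol B, 1 without either untreated wild-type library and 8 without either untreated knockout library, and 17 with DESeq2. Of 8 branched-chain amino acid genes, ilvD was the 1 called (4 lower adjusted over the list alone), with a median of -0.88 (camera adjusted p = 4.76e-06; adjusted p = 0.652 with an estimated correlation). The protease list held clp genes, ftsH, lonA and lonB, and also ctsR and htpG. Of its 11 genes, clpY was the 1 called (3 higher adjusted over the list alone), with a median of 0.40. Its camera adjusted p was 0.0144, its adjusted p = 0.3997 with an estimated correlation, and its fry adjusted p 0.00413. In the region of ole, BH2778 and BH2779 were at 175% and 179% of wild type (log2 0.81 ± 0.18 and 0.84 ± 0.19), with edgeR adjusted p-values of 0.0620 and 0.0688 over all genes (with DESeq2 BH2779 was called, adjusted p = 0.0249; 3 higher of 17 neighbours adjusted over the list alone). BH2780 stood at -0.86 ± 0.29 (edgeR adjusted p = 0.217), with -1.46 without the knockout library ethanol A and -0.47 without ethanol B.

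**Figure D4:**
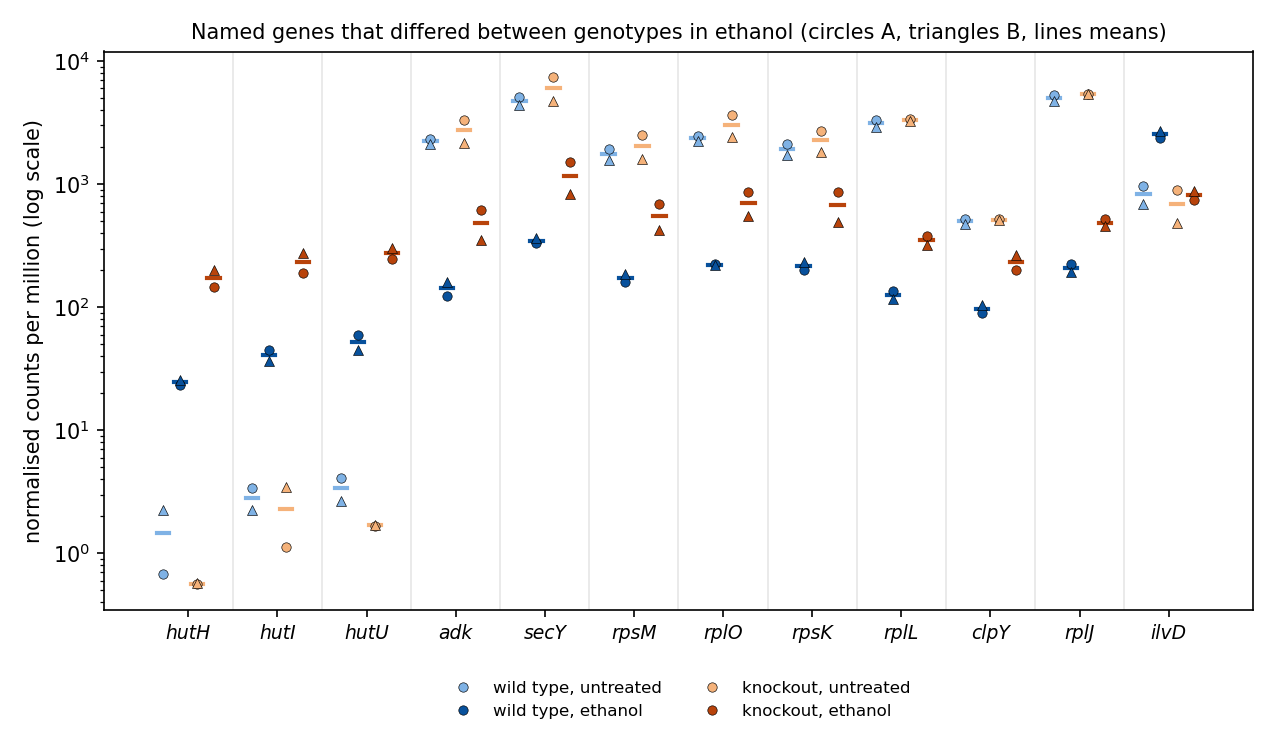
Normalised CPM (log scale) of the 12 named genes with a symbol, other than OLE, that differed between genotypes in ethanol, in each of the 8 libraries; circles are libraries A, triangles libraries B and lines the means of 2. hutH lay at 174 CPM in the ethanol-treated knockout and 24.5 CPM in ethanol-treated wild type, with 0.566 CPM in the untreated knockout and 1.46 CPM in untreated wild type.

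The interaction tests whether the ethanol response itself differed between the genotypes. No gene passed: edgeR's quasi-likelihood test called 0 of 3474 genes at an adjusted p of 0.05, 264 had an unadjusted p under 0.05 and DESeq2 called 6. The smallest p-values, none of which passed, belonged to hutU (log2 3.32 ± 0.58, knockout minus wild type), BH1807 (2.29 ± 0.39), BH3121 (1.58 ± 0.26), BH0843 (-2.08 ± 0.36) and BH3390 (-1.61 ± 0.28), each at an edgeR adjusted p of 0.133. With DESeq2, BH3390 (adjusted p = 0.0262), BH3121 (0.0403) and BH0843 (0.0403) passed. In simulated data at this depth, with untreated wild-type levels in every group, the test recovered 51% of 4-fold and 8% of 2-fold differences. The count was 10 without the wild-type library untreated B. With library totals as the only scaling, the median interaction of all genes moved from log2 0.05 to 0.17.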

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

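The rules that flagged these results were planned, while every technical test weighed in the closing section was chosen after its result had been seen. The first group was flagged because the ethanol response of a list differed between knockout and wild type in a camera or fry test of that difference. The median interaction (log2) was 0.56 for ribosomal proteins (camera adjusted p = 5.85e-09; adjusted p = 0.757 with an estimated correlation) and 1.46 for sugar transporters and glycosidases (camera adjusted p = 5.60e-05; adjusted p = 0.757 with an estimated correlation). It was -0.65 for branched-chain amino acid synthesis (camera adjusted p = 6.02e-04; adjusted p = 0.757 with an estimated correlation) and 0.36 for flagella (camera adjusted p = 0.00496; adjusted p = 0.785 with an estimated correlation). For the protease list, which also holds ctsR and htpG, it was 0.19, with an adjusted p of 0.0389 by fry, 0.116 by camera and adjusted p = 0.757 with an estimated correlation. None of these lists had a called member over all genes. In 9 of the 24 sugar genes, among them rbsA, the wild-type untreated library A stood apart, and without it the median interaction of that list was 0.46. Without it the other medians were 0.43 for ribosomal proteins, -0.88 for branched-chain amino acid synthesis, 0.19 for flagella and 0.13 for the protease list. The last result, the rRNA share, lies outside the genes compared: it was 9.90 percentage points higher in ethanol than in untreated libraries (exact permutation p = 0.0286).

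Between the ethanol-treated knockout and wild type the ribosomal protein list had a median of 0.91 (camera adjusted p = 6.89e-21), but adjusted p = 0.388 with an estimated correlation, 0.0805 by fry, and 5 of 53 members called. A single knockout library did not carry this, since the median difference from the wild-type mean was 0.887 in library A and 0.714 in library B. The median of the list minus that of all genes was at least 0.884 under 3 other scalings. A change of scaling shifts all genes of a library nearly alike, so that measure could hardly move. It leaves open how far the scaling sets the 0.91 itself. RNA like that of untreated cells in the ethanol-treated knockout would also raise flagellar genes, which had a median of 0.15, and the difference between these lists was 0.752 (95% bootstrap interval 0.293 to 0.931; permutation p = 2.0e-05). That interval reaches the limit set for the test, and operon genes are not independent, so this test cannot decide. Such RNA would also keep each gene at or above the same share of its untreated level. In the knockout lytE, fruB, fruA and treA changed by log2 -5.02, -5.003, -4.95 and -4.94, while the ribosomal protein list stood at -3.22 in wild type. These values argue against such RNA as the source of the whole 0.91. A smaller share cannot be told apart from a weaker response of the knockout.

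The wild-type untreated library A stood more than 3-fold from the median of the other untreated libraries in 91 of 3473 genes, 58 higher and 33 lower. Shallower sequencing does not account for this, because at equal depth the other libraries had at most 17 such genes and this library had 93. Of these genes 59.3% (54 of 91; exact 95% interval 48.5 to 69.5) deviated in the direction of the ethanol response of the knockout. The interval is wide and operon genes are not independent, so the 59.3% alone does not decide whether the library held RNA of ethanol-treated cells. Strongly induced genes, however, stayed low in both untreated wild-type libraries. pckA lay at 7.34 ± 1.64 CPM there and at 7140 with ethanol, gapB at 38.1 ± 13.2 and 22506, and dps at 46.2 ± 2.64 and 2914. For these genes the values argue against such RNA as the source of the deviations, though a trace is not excluded. In 78.0% of the genes (71 of 91; exact 95% interval 68.1 to 86.0) the wild-type ethanol library A deviated from B in the same direction. A batch shared by the wild-type A libraries therefore cannot be told apart from chance differences between libraries, as the labels name no batch and a single pair of libraries was compared. The untreated knockout libraries were not part of that test and went both ways. In them argG was higher in A than in B (37.0 and 12.6 CPM), as in wild type, and so was lctP (417 and 225 CPM), unlike in wild type. Over all 3474 genes the A minus B deviations of untreated wild type and knockout had a correlation of 0.256.

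tRNA reads fell with ethanol in both genotypes. A loss of short RNAs during preparation could lower 5S rRNA as well. The 5S log2 change was at most 0.460 of that of tRNA in the 4 library pairs with the same genotype and letter (lowest -0.207). However, 5S is itself rRNA, whose share depends on the depletion and rose from 61.0% in untreated to 70.9% in ethanol libraries. A rise of that kind could hide a loss of 5S, so this test cannot decide whether short RNAs were lost. Reads moved between near-identical tRNA copies would leave the summed share unchanged, whereas that share fell 8.85-fold to 12.9-fold. No biological explanation was tested, because ethanol and time in the closed tubes were not separated.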

How the results depend on the processing

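Of 4760 alternative values for 230 gene results, 4611 kept their direction and side of the threshold, 136 lost the call, 13 gained it and 0 reversed. Of 1795 counts for 87 list results, 1672 stayed within 1.5 times the reported count. The counts for ethanol stayed within 1.5 times under every setting. Where they did not, the cause was not tested unless given.

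Between untreated genotypes (reported 1), DESeq2 called 5, and 0 were called without the 10 most abundant genes or without tRNA and other RNA genes, because both remove OLE. Leaving out a library gave 1 to 15. Between genotypes in ethanol (reported 34), the counts were 20 with upper-quartile scaling, 86 with DESeq2, 61 with no filter, 21 with rRNA genes kept, 1 with only the 4 samples compared, 16 without a robust prior and 7 to 34 without a library. With library totals as scaling 89.4% of 47 calls were rises in place of 79.4%, and the median moved from 0.01 to 0.12. For the interaction (reported 0), DESeq2 called 6 and leaving out a library gave 0 to 10. A lone remaining library was assumed to vary like the other groups.

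The labels do not say whether a shared letter pairs libraries. Correlations of the A minus B deviations were 0.269 (untreated and ethanol wild type) and 0.256 (untreated wild type and knockout), and -0.089 to 0.080 for the other pairs of groups. With the letter as a replicate block the counts were 2395, 2279, 1, 43 and 0 in the order of the report. With genotype and letter as a block they were 2381 and 2267 for ethanol and 21 for the interaction, with hutU (adjusted p = 0.0475), BH1807 (0.0475), BH3121 (0.0479), BH0843 (0.0475) and BH3390 (0.0479) called. The letter block left 7 lists in place of 8 called by camera for ethanol in wild type (the tricarboxylic acid cycle had an adjusted p of 0.0612) and changed no other number of lists called.

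Over 27 lists, camera with an estimated correlation called 0 in each of the 5 comparisons. fry called 19 (camera 8) for ethanol in each genotype, 0 (camera 5) between untreated genotypes, 1 (camera 3) between genotypes in ethanol and 1 (camera 4) for the interaction. In simulated data built on untreated wild-type levels, 4.13% to 11.9% of calls were false, and recovery was lowest for the interaction.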

Other observations

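Further lists, fixed before the data were examined, moved with ethanol in part. Of 19 genes of the SOS and DNA repair list, 12 were higher and 2 lower in wild type and 10 and 2 in the knockout (edgeR, adjusted p under 0.05, the same over the list alone), with lexA, the SOS repressor, at log2 2.47 ± 0.31 and 1.76 ± 0.30. Its largest rises, mutB (4.80 ± 1.04 in wild type) and mutA (3.43 ± 0.65), are symbols of methylmalonyl-CoA mutase in other bacteria. The counts of rises may thus include genes outside DNA repair. mutB had 33.6 CPM in the wild-type untreated library A and 4.47 in B, and its call in wild type was lost when only the 4 samples compared were fitted (adjusted p = 0.0590). Without the wild-type library ethanol A, mutB stood at 3.56, mutA at 2.29 and sspA of the sporulation list at 3.64. mutB reached 6.77 without untreated A, mutA 4.07 without ethanol B and sspA 6.16 without untreated B. The 14 calls in wild type became 8 without the wild-type library ethanol A and 9 without untreated B, and the 12 in the knockout became 7 without its library untreated B. Of 42 sporulation genes, 17 were higher and 10 lower in wild type and 13 and 10 in the knockout, with sspA, of a small spore protein, at 4.91 ± 0.77 and 5.17 ± 0.86. Camera called neither list, with adjusted p-values of 0.1698 and 0.686 in wild type and 0.158 and 0.704 in the knockout.

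Cell envelope genes went both ways. Of 7 genes of a list of phospholipid synthesis genes with tagG and tagH, 5 were lower and 1 higher in each genotype (camera adjusted p = 0.325 and 0.167). gpsA stood at -2.36 ± 0.20 in wild type and -2.32 ± 0.20 in the knockout, and pssA, phosphatidylserine synthase, at 1.41 ± 0.24 and 1.17 ± 0.24. Of 27 cell wall genes 9 were higher and 11 lower in wild type and 8 and 10 in the knockout, with murZ at 2.64 ± 0.22 and 2.35 ± 0.22 (camera adjusted p = 0.822 and 0.538). Among compatible solute genes ectC rose in the knockout too (4.64 ± 0.31), and opuD, for an uptake protein, fell in both genotypes (-4.03 ± 0.27 and -3.56 ± 0.27). sodA, superoxide dismutase, rose by 2.05 ± 0.33 in wild type and 2.15 ± 0.33 in the knockout. aldA rose in the knockout by 2.45 ± 0.24, while adhB stood at -1.62 ± 0.50 (edgeR adjusted p = 0.0170), a call lost without the knockout library ethanol A (adjusted p = 0.142) or untreated B (adjusted p = 0.0922), or with DESeq2 (adjusted p = 0.0645).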
